A study of Mus musculus with 10 samples.

How the data were processed

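The series holds 10 RNA-seq libraries of mesenchymal cells that were isolated by flow cytometry from the Peyer's patches of C57BL/6 mice. Per the labels, total RNA was extracted with a column kit for small samples and cDNA was made and amplified with the SMART-Seq v4 kit for ultra-low input, which does not mark strand. One deposited table per library lists 47643 genes with coordinates, exon length and read numbers. Per the file headers, each table gives the authors' counts of total exon reads, unique exon reads and gene reads (exon and intron), together with RPKM and TPM values. Coordinates are those of the deposited tables, and GRCm38 is the build named in the submitters' processing notes. The aligner, its version and the gene annotation are not given in the sources used here.

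The deposited counts of total exon reads were the measurement used for the tests, since they are whole numbers that are not normalised. The deposited RPKM values equalled exon reads divided by exon length and by the total gene reads of the library, and were used only as an alternative. The deposited TPM values were not used. Of the gene identifiers, 47224 of 47643 were present in GENCODE M21, and 59 gene names that ended in a numbered suffix were given the symbol of their identifier there. For 16517 genes the tables list an exon length of 0 and no exon reads; these held at most 2.57% of the gene reads of a library and were not tested. No table had a line without a gene identifier.

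Libraries were grouped by the MAdCAM1 label into MCi (MAdCAM1-negative, n = 5) and MRC (MAdCAM1-positive, n = 5), and each contrast is MRC minus MCi. Total exon reads per library were 4091438, 4255530, 3941032, 6603603 and 8738115 in MCi 1 to 5 and 4355386, 4141949, 4761017, 7004048 and 6142562 in MRC 1 to 5. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total count of 15, which left 12127 genes. TMM factors and edgeR 4.0.16 (quasi-likelihood fit with robust estimation, R 4.3.3) gave log2 fold changes, and P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Expression is given as CPM (exon reads relative to the library total scaled by its TMM factor), as mean and SD over the 5 libraries of a group. Read copies made by PCR were not removed by molecular identifiers, so floors, computed from the unscaled totals, cover counting error only.

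The comparison, the alternatives, 30 gene lists and the rule for named genes were set before the data were examined. Of the lists, 19 hold programmes of stromal and immune biology and 11 hold markers of other cell types that the gate could hold. The erythroid list had no member with enough reads to be tested, and 1 of its 8 genes, Ahsp, was not analysed here. The other 29 were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the 29 lists. The rule names the sorting antigens with Tnfsf11 and Cxcl13; the 12 genes with the largest absolute log2 fold change in each direction among those past the threshold with a mean of at least 10 CPM in the higher group; and from each list up to 4 members with the smallest p. It named 125 genes, of which 123 were tested; results of some of them are not reported here. Madcam1 and the other sorting antigens define the gates and are not findings between them.

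Alternatives set in advance were DESeq2 1.42.0; its size factors or upper-quartile factors in edgeR; no filter, or at least 5 CPM in 5 libraries; the replicate number as a block, without and with a correction for exon length; leaving out each library; limma on log2(RPKM + 1) or log2(RPKM + 0.1) for genes of at least 1 RPKM in 5 libraries, and without that filter; and a threshold of 0.01. For lists, camera with an estimated correlation and fry were added to these. Chosen after the data were seen were leaving out MRC4 and MRC5, unique exon reads, gene reads, an epithelial score as a covariate, replicates 1 to 3 or 4 and 5 alone, and a covariate for these library sets. A list score is the mean log2 CPM of its tested members, with a prior count of 2.

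The procedure was tested on simulated counts for the 12127 genes with the means and depths of these libraries. It called 16.0% of genes changed 2-fold, 71.4% of those changed 4-fold, 83.7% of those changed 8-fold and 93.9% of those changed 16-fold, along with 7 unchanged genes. Simulated counts were drawn independently for each gene, without the differences that many genes share between libraries of a group. Rates in the real data may therefore differ. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.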

Results

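Peyer's patches are the organised lymphoid follicles in the wall of the small intestine. RNA was sequenced from podoplanin-positive mesenchymal cells of mouse Peyer's patches that lacked CD45 (leukocytes), EpCAM1 (epithelium), TER119 (erythroid cells) and CD31 (endothelium). A gate on MAdCAM1, an adhesion molecule bound by lymphocyte integrins, divided these cells into a negative population called MCi (n = 5 libraries) and a positive population called MRC (n = 5 libraries). The comparison asks how the transcriptomes of these populations differ. Libraries held 3941032 to 8738115 total exon reads, and a count of 3 reads corresponded to 0.343 to 0.761 CPM of the unscaled totals. The labels do not say which libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

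The BMP ligand genes Bmp7, Bmp5 and Bmp3 were higher in MCi. Bmp7 (ENSMUSG00000008999, GRCm38 chromosome 2, 172868012 to 172940321, minus strand) averaged 143 ± 30.2 CPM (SD, n = 5) in MCi and 16.4 ± 5.29 CPM in MRC, 8.73-fold higher in MCi. Its log2 fold change, MRC minus MCi, was −3.13 ± 0.27 (SE; edgeR quasi-likelihood adjusted p = 0.00106). Bmp5 (chromosome 9, 75775364 to 75900310) averaged 347 ± 83.2 CPM in MCi and 102 ± 14.4 CPM in MRC, a log2 fold change of −1.77 ± 0.21 (edgeR adjusted p = 0.00483). Bmp3 (chromosome 5, 98854415 to 98884396) averaged 94.7 ± 31.6 CPM in MCi and 13.2 ± 8.75 CPM in MRC, a log2 fold change of −2.83 ± 0.43 (edgeR adjusted p = 0.0198). For each of these 3 genes, every MCi library lay above every MRC library. Of the 16 subepithelial telocyte and BMP ligand genes tested, 3 were higher in MCi and 13 did not pass over all genes; adjusted over the list alone, 6 were higher in MCi. Their median log2 fold change was −0.83, with 15 of 16 below 0 (camera adjusted p = 2.07e-13, and adjusted p = 0.00172 with an estimated correlation). F3, which encodes tissue factor, had a log2 fold change of −1.60 ± 0.30 and did not pass (edgeR adjusted p = 0.0505). Leaving out 1 library ended the call of Bmp3 for MCi1, MCi2, MCi5, MRC2 and MRC3 (adjusted p = 0.0767, 0.0571, 0.0611, 0.0525 and 0.0549; 2.11e-08 to 0.0828 over 27 alternatives), while Bmp7 and Bmp5 passed in each of the 10 such fits.

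Contractile and vascular mural genes were also higher in MCi. Acta2 (chromosome 19, 34241090 to 34255336), which encodes smooth muscle actin, averaged 1333 ± 293 CPM (SD, n = 5) in MCi and 446 ± 96.5 CPM in MRC (log2 fold change −1.58 ± 0.22, edgeR adjusted p = 0.0140). Kcnj8 (chromosome 6, 142564837 to 142571614), the pore subunit of a potassium channel of mural cells, averaged 188 ± 71.8 CPM in MCi and 17.7 ± 8.16 CPM in MRC, 10.7-fold higher in MCi (log2 fold change −3.41 ± 0.39, edgeR adjusted p = 0.00483). Of the 16 smooth muscle and pericyte genes tested, 2 were higher in MCi and 14 did not pass; adjusted over the list alone, 9 were higher in MCi. The median log2 fold change was −1.50, with 14 of 16 below 0 (camera adjusted p = 1.41e-12, and adjusted p = 0.0443 with an estimated correlation). Abcc9, the regulatory partner of the Kcnj8 channel, had a log2 fold change of −2.62 ± 0.54, and the actin-binding gene Tagln one of −1.62 ± 0.32, with edgeR adjusted p of 0.0673 and 0.0583. Not every member had a lower mean in MRC: Des, an intermediate filament gene of muscle, averaged 151 ± 37.9 CPM in MCi and 186 ± 121 CPM in MRC, while the pericyte gene Rgs5 averaged 562 ± 219 and 536 ± 194 CPM, a difference smaller than the spread within either group. The call of Acta2 ended without MCi1, MCi2 or MCi5 (adjusted p = 0.0509, 0.0606 and 0.0611; 8.26e-10 to 0.0611 over 27 alternatives), and that of Kcnj8 held in each of the 10 fits that left out 1 library.

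**Figure D1:**
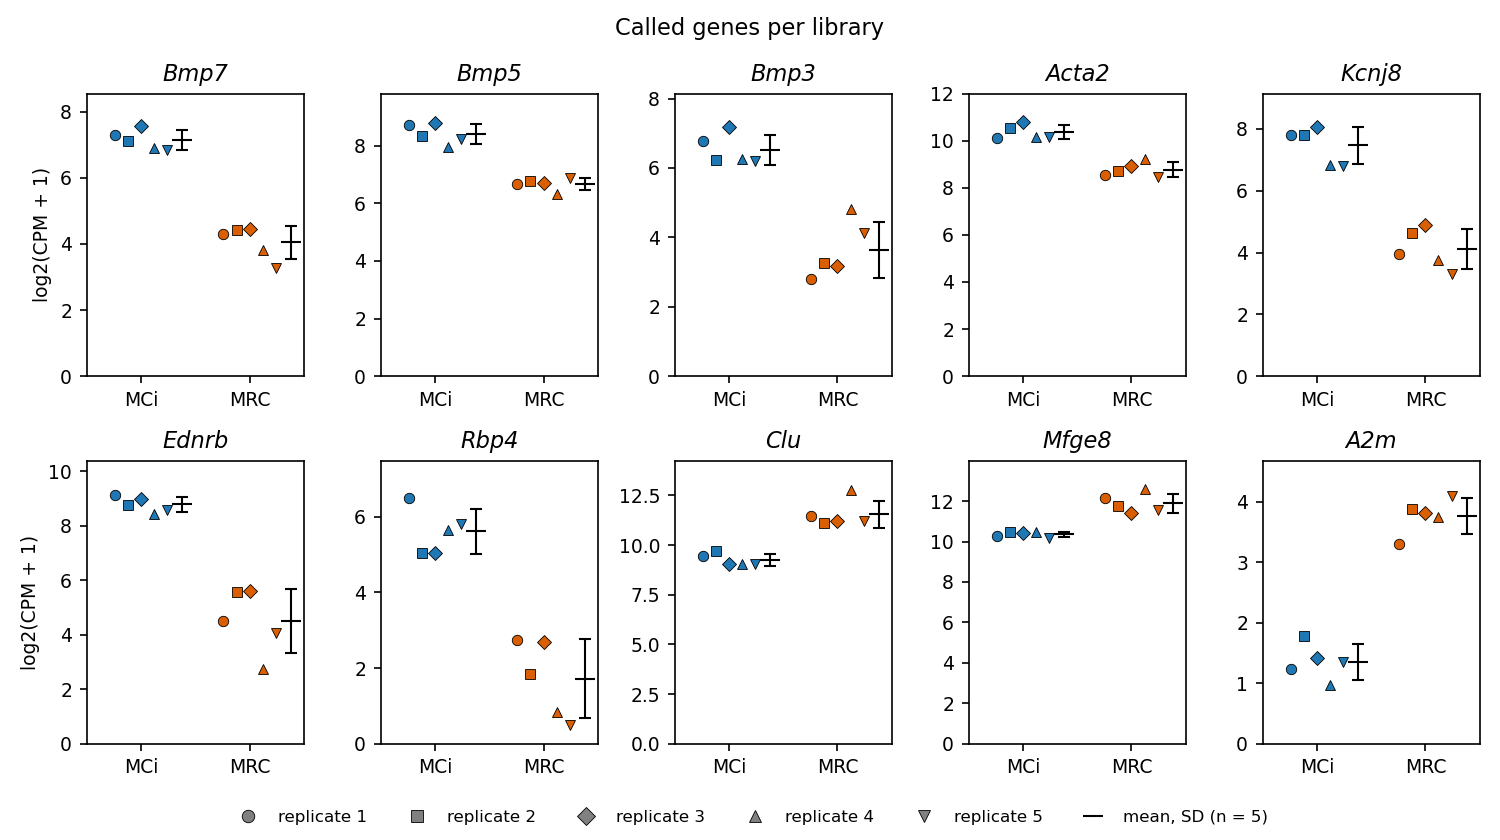
Expression of 10 genes in each library, as log2(CPM + 1) on the vertical axis, with one point per library and the mean and SD of the log values for MCi (n = 5) and MRC (n = 5). Each gene is drawn on its own scale starting at 0; Bmp7, Bmp5, Bmp3, Acta2, Kcnj8, Ednrb and Rbp4 lie higher in all MCi libraries, and Clu, Mfge8 and A2m in all MRC libraries.

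Other genes with large differences toward MCi were Ednrb, Rbp4, Fgf9, Palmd, Bean1, Pla1a and Sv2b. Ednrb (chromosome 14, 103814625 to 103844173), the endothelin B receptor gene, averaged 445 ± 85.7 CPM (SD, n = 5) in MCi and 27.5 ± 18.8 CPM in MRC, 16.2-fold higher in MCi (log2 fold change −4.02 ± 0.53, edgeR adjusted p = 0.0107). Rbp4 (chromosome 19, 38116620 to 38125321), which encodes the plasma carrier of retinol, averaged 51.7 ± 23.6 CPM in MCi and 2.99 ± 2.52 CPM in MRC (log2 fold change −4.13 ± 0.65, edgeR adjusted p = 0.0257). Fgf9, a fibroblast growth factor gene, averaged 17.9 ± 3.98 and 1.54 ± 0.947 CPM (edgeR adjusted p = 0.0297). Palmd, Bean1, Pla1a and Sv2b, a synaptic vesicle protein gene, had log2 fold changes of −4.44, −3.88, −3.45 and −5.82 (edgeR adjusted p = 0.0323, 0.0389, 0.0305 and 0.0271). Of 10 retinoid metabolism genes tested, Rbp4 was higher in MCi and 9 did not pass; adjusted over the list alone, 1 was higher in MRC and 2 in MCi (camera adjusted p = 0.545). Ednrb passed in each fit that left out 1 library, whereas the call of Rbp4 ended without MCi1, MCi2, MCi4, MCi5, MRC2 or MRC3 (adjusted p = 0.0787, 0.0571, 0.0745, 0.0743, 0.0710 and 0.0528, within 1.70e-09 to 0.0787 over 27 alternatives). Leaving out 1 library gave adjusted p up to 0.0865 for Fgf9, 0.118 for Palmd, 0.107 for Bean1, 0.0882 for Pla1a and 0.0811 for Sv2b. In those fits Fgf9 and Pla1a passed without MRC5 alone, Palmd without MRC4 or MRC5, Bean1 without MRC2 or MRC4, and Sv2b without MCi4, MRC2 or MRC5. Log2 fold changes moved to −6.91 for Sv2b and −4.51 for Bean1 without MRC2, and to −5.08 for Palmd without MRC3.

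Genes of the mesothelium, the cell layer that covers the outer gut wall, had the largest fold changes toward MCi and varied widely among MCi libraries. Msln (chromosome 17, 25748614 to 25754327), which encodes mesothelin, was at 41.0, 24.2, 3.35, 232 and 218 CPM in MCi 1 to 5 and at 0 to 0.472 CPM in MRC, with 4084 reads in MCi and 6 in MRC (log2 fold change −8.60 ± 1.39, edgeR adjusted p = 0.0315). Gpm6a, a neuronal and mesothelial membrane glycoprotein gene, had 3158 reads in MCi and 9 in MRC (log2 fold change −7.58 ± 1.29, edgeR adjusted p = 0.0400). Slpi, a secreted protease inhibitor gene, had 13528 and 31 reads (−8.06 ± 1.36, edgeR adjusted p = 0.0389), and Plet1 had 394 and 4 reads (−5.82 ± 1.04, edgeR adjusted p = 0.0389), the 4 reads all in MRC3. Of 6 mesothelium markers tested, 2 were higher in MCi and 4 did not pass; adjusted over the list alone, 5 were higher in MCi. The median log2 fold change was −6.37 (camera adjusted p = 1.99e-06, and adjusted p = 0.204 with an estimated correlation). This median ranged from −7.74 (without MRC4) to −5.73 (without MCi5) when 1 library was left out. Leaving out any library but MCi3 ended the call of Msln (adjusted p = 0.0545 to 0.0907), and without both MRC4 and MRC5 its adjusted p was 0.157, within 1.55e-09 to 0.157 over 26 alternatives. Slpi and Gpm6a likewise passed without MCi3 and in no other fit that left out 1 library (adjusted p up to 0.104 and 0.106), and Plet1 passed in 0 of these 10 edgeR fits (0.0560 to 0.117), having an adjusted p of 0.0389 over all libraries. The fitted log2 fold changes moved with single libraries: Slpi to −9.18 without MRC5, Gpm6a to −6.75 without MCi5 and −8.18 without MRC2, and Plet1 to −8.90 without MRC3, where no MRC read remained and the fitted value is no bound.

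Among the genes higher in MRC were Clu, Mfge8 and A2m, which encode secreted glycoproteins. Clu (chromosome 14, 65968483 to 65981548), which encodes the extracellular chaperone clusterin, averaged 3330 ± 1998 CPM (SD, n = 5) in MRC and 626 ± 141 CPM in MCi, 5.32-fold higher in MRC (log2 fold change 2.41 ± 0.36, edgeR adjusted p = 0.0197). Mfge8 (chromosome 7, 79133768 to 79149060), which encodes a bridging protein for the uptake of apoptotic cells, averaged 4000 ± 1399 CPM in MRC and 1326 ± 111 CPM in MCi (log2 fold change 1.59 ± 0.25, edgeR adjusted p = 0.0254). A2m (chromosome 6, 121635376 to 121679227), a protease inhibitor gene, averaged 12.8 ± 2.63 CPM in MRC, was at 0.970 to 2.44 CPM in MCi, and was 8.02-fold higher in MRC (edgeR adjusted p = 0.00440). The thyroid hormone receptor gene Thrb averaged 20.5 ± 6.88 CPM in MRC and 4.06 ± 2.24 CPM in MCi, and Extl1, of heparan sulphate synthesis, 18.5 ± 2.14 and 5.66 ± 1.74 CPM (edgeR adjusted p = 0.0389 and 0.0164). Lima1, an actin-binding gene, had a log2 fold change of 1.01 ± 0.19 (edgeR adjusted p = 0.0488). Ugt1a6a had one of 1.21 ± 0.21 (edgeR adjusted p = 0.0315), but shares exons with neighbouring Ugt1a genes, so its reads are uncertain. Fcho1, named after its values were seen because its mean in MRC was 9.93 CPM, had a log2 fold change of 3.23 ± 0.50 (edgeR adjusted p = 0.0237; it passed in 4 of 10 fits that left out 1 library) and completed the 9 genes higher in MRC together with Madcam1 of the gate.

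Of these, A2m passed in each fit that left out 1 library. The call of Clu ended without MCi1, MCi2, MCi3, MCi4 or MCi5 (adjusted p = 0.0767, 0.0538, 0.0686, 0.0754 and 0.0743, within 2.35e-09 to 0.0767 over 27 alternatives). That of Mfge8 ended without MCi1, MCi2, MCi3, MCi4, MCi5 or MRC1 (adjusted p = 0.0837, 0.0685, 0.0782, 0.0805, 0.0753 and 0.0547, within 1.06e-08 to 0.0837). Extl1 missed the threshold without MCi1, MCi4, MCi5 or MRC3 (up to 0.0745), Thrb without any but MCi3 and MRC4 (up to 0.142), Ugt1a6a without any but MRC4 (up to 0.114) and Lima1 without any of the 10 (0.0542 to 0.150).

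Genes of lymphoid stroma and marginal reticular cells leaned toward MRC as a list, with no single member past the threshold. Cxcl13 (chromosome 5, 95956951 to 95961068), the B cell attracting chemokine gene, averaged 166 ± 72.6 CPM (SD, n = 5) in MRC and 66.1 ± 30.1 CPM in MCi (log2 fold change 1.32 ± 0.38, edgeR adjusted p = 0.166). Ccl19, a chemokine gene of T cell zones, averaged 650 ± 278 and 239 ± 128 CPM (1.44 ± 0.39, edgeR adjusted p = 0.145), and Enpp2, which encodes autotaxin, 310 ± 78.9 and 157 ± 76.6 CPM (0.98 ± 0.33, edgeR adjusted p = 0.213). Bst1 was at 1.67 to 6.32 CPM in MCi and at 19.8, 16.1, 19.7, 122 and 119 CPM in MRC 1 to 5 (3.70 ± 0.72, edgeR adjusted p = 0.0633). Of the 11 members tested, 0 passed over all 12127 genes in edgeR, where 4 had an unadjusted p under 0.05, and DESeq2 called 3; adjusted over the list alone, 4 were higher in MRC. The median log2 fold change was 0.45 (camera adjusted p = 0.00150, and adjusted p = 0.0990 with an estimated correlation). Tnfsf11 (chromosome 14, 78277445 to 78308043), which encodes the M cell differentiation factor RANKL, had 55 reads over the MCi libraries and 19 over the MRC libraries, at 0 to 2.90 CPM, too few to be tested.

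Follicular dendritic cell markers were divided. Mfge8 and Clu were higher in MRC and 7 of the 9 members tested did not pass; adjusted over the list alone, 4 were higher in MRC and 3 in MCi. The antibody receptor gene Fcgr2b averaged 22.0 ± 12.4 CPM (SD, n = 5) in MCi and 2.53 ± 3.39 CPM in MRC (log2 fold change −3.12 ± 0.91, edgeR adjusted p = 0.172). Its log2 fold change ranged from −4.39 to −2.78 when 1 library was left out. The list as a whole did not pass (median 0.25, camera adjusted p = 0.298). Beside these values stand the epithelial levels of the MRC libraries: Epcam was at 0.239, 23.3, 107, 910 and 861 CPM in MRC 1 to 5.

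**Figure D2:**
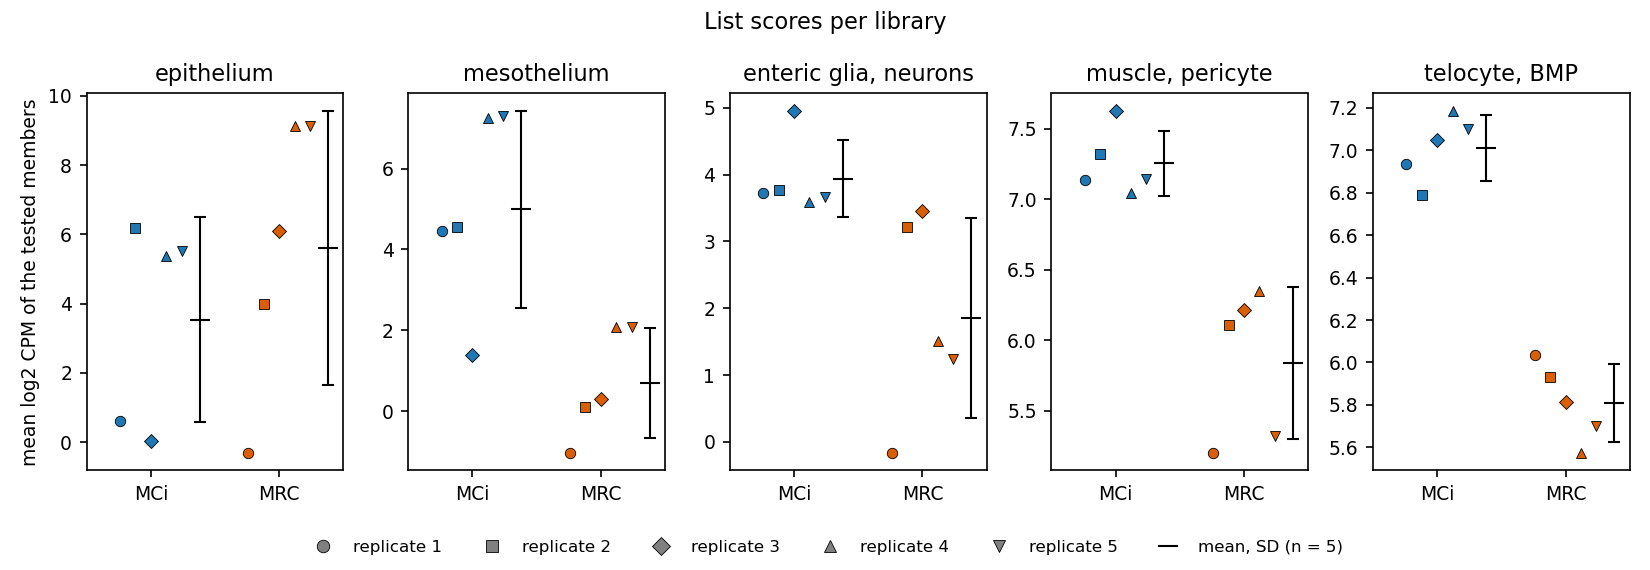
Scores of 5 gene lists in each library (mean log2 CPM of the tested members, vertical axis, each panel on its own scale), with one point per library and the mean and SD for MCi (n = 5) and MRC (n = 5). The epithelial score ranges from 0.02 to 6.17 in MCi and from −0.31 to 9.14 in MRC, where MRC4 and MRC5 are highest.

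Intestinal epithelial transcripts were high in MRC4 and MRC5, although EpCAM1-positive cells were gated out. Epcam (chromosome 17, 87635979 to 87651106) was at 0, 69.4, 0.479, 59.1 and 49.7 CPM in MCi 1 to 5, against 910 and 861 CPM in MRC4 and MRC5. Fabp2, the fatty acid binding protein gene of enterocytes, reached 4843 CPM in MRC4, 8582 CPM in MRC5 and 944 CPM in MRC3, and 1.20 to 152 CPM in MCi. The microvillus gene Vil1 reached 1413 and 1588 CPM in MRC4 and MRC5. Of 15 epithelial markers, 0 passed in edgeR over all genes or adjusted over the list alone, 3 had an unadjusted p under 0.05 and DESeq2 called 2. All 15 fitted changes were above 0 (median 3.14, camera adjusted p = 0.00296, and adjusted p = 0.735 with an estimated correlation). That list call ended without MRC4 (camera adjusted p = 0.0750), without MRC5 (0.0631) and without both (0.763), within 3.87e-28 to 0.763 over 29 alternatives. The median was 2.58 without MRC4, 2.55 without MRC5 and 0.29 without both. Reads of mitochondrial genes made up 6.66% and 4.28% of exon reads in MRC4 and MRC5 and 0.706% to 1.58% in the other 8 libraries.

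Transcripts of the other sort antigens were also measured. Madcam1 (chromosome 10, 79664574 to 79668536) averaged 49.4 ± 22.5 CPM (SD, n = 5) in MRC and 1.34 ± 1.05 CPM in MCi. Pdpn averaged 79.2 ± 17.8 CPM in MCi and 54.1 ± 28.7 CPM in MRC (edgeR adjusted p = 0.504). It was at 81.4, 77.7, 64.4, 21.4 and 25.6 CPM in MRC 1 to 5, lowest in MRC4 and MRC5. Without both of these its log2 fold change was −0.08. Ptprc, which encodes CD45, was at 0.138 to 2.63 CPM in MCi and at 0.955, 0.777, 4.81, 3.31 and 10.9 CPM in MRC 1 to 5 (edgeR adjusted p = 0.439). Pecam1, which encodes CD31, was at 0 to 2.40 CPM, below the filter. Of the B cell markers only Spib had enough reads (43.9 ± 20.8 CPM in MRC and 13.9 ± 4.41 CPM in MCi, edgeR adjusted p = 0.0633). As a list of 1 gene its camera adjusted p was 0.00532 (adjusted p = 0.0990 in the estimated-correlation setting, though 1 gene has no correlation to estimate). It passed in DESeq2, and its pass over the list alone only restates its unadjusted p.

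Enteric glia, interstitial cells of Cajal (pacemaker cells of gut muscle) and basement membrane genes had lower medians in MRC without a member past the threshold over all genes in edgeR, while 4, 3 and 4 members had an unadjusted p under 0.05 and DESeq2 called 3, 2 and 2. Among 9 glial and neuronal markers the median was −2.19, with 2 higher in MCi adjusted over the list alone (camera adjusted p = 0.000465, and adjusted p = 0.391 with an estimated correlation). The neural crest factor gene Sox10 averaged 40.7 ± 25.2 CPM (SD, n = 5) in MCi and 5.73 ± 6.32 CPM in MRC (edgeR adjusted p = 0.196). Among 4 markers of interstitial cells of Cajal the median was −0.98 (camera adjusted p = 0.00156, and adjusted p = 0.204 with an estimated correlation). Adjusted over the list alone, 3 were higher in MCi, namely Ano1, Etv1 and Gja1. The remaining marker, Kit, had log2 fold changes of −1.65 to 0.247 when 1 library was left out (edgeR adjusted p = 0.670 to 0.989). Among 14 basement membrane genes the median was −0.54, with 2 higher in MCi adjusted over the list alone (camera adjusted p = 0.000465, and adjusted p = 0.602 with an estimated correlation). Without MRC4 and MRC5 the basement membrane median was −0.16 (camera adjusted p = 0.0251, within 2.00e-07 to 0.602 over 29 alternatives) and the glial and neuronal median −1.41 (camera adjusted p = 0.000444, within 2.45e-06 to 0.391). Col4a6, a type IV collagen gene, averaged 44.3 ± 15.4 CPM in MCi and was at 3.34, 9.32, 9.83, 0.315 and 0.199 CPM in MRC 1 to 5, the last 2 being the libraries with Epcam at 910 and 861 CPM.

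**Figure D3:**
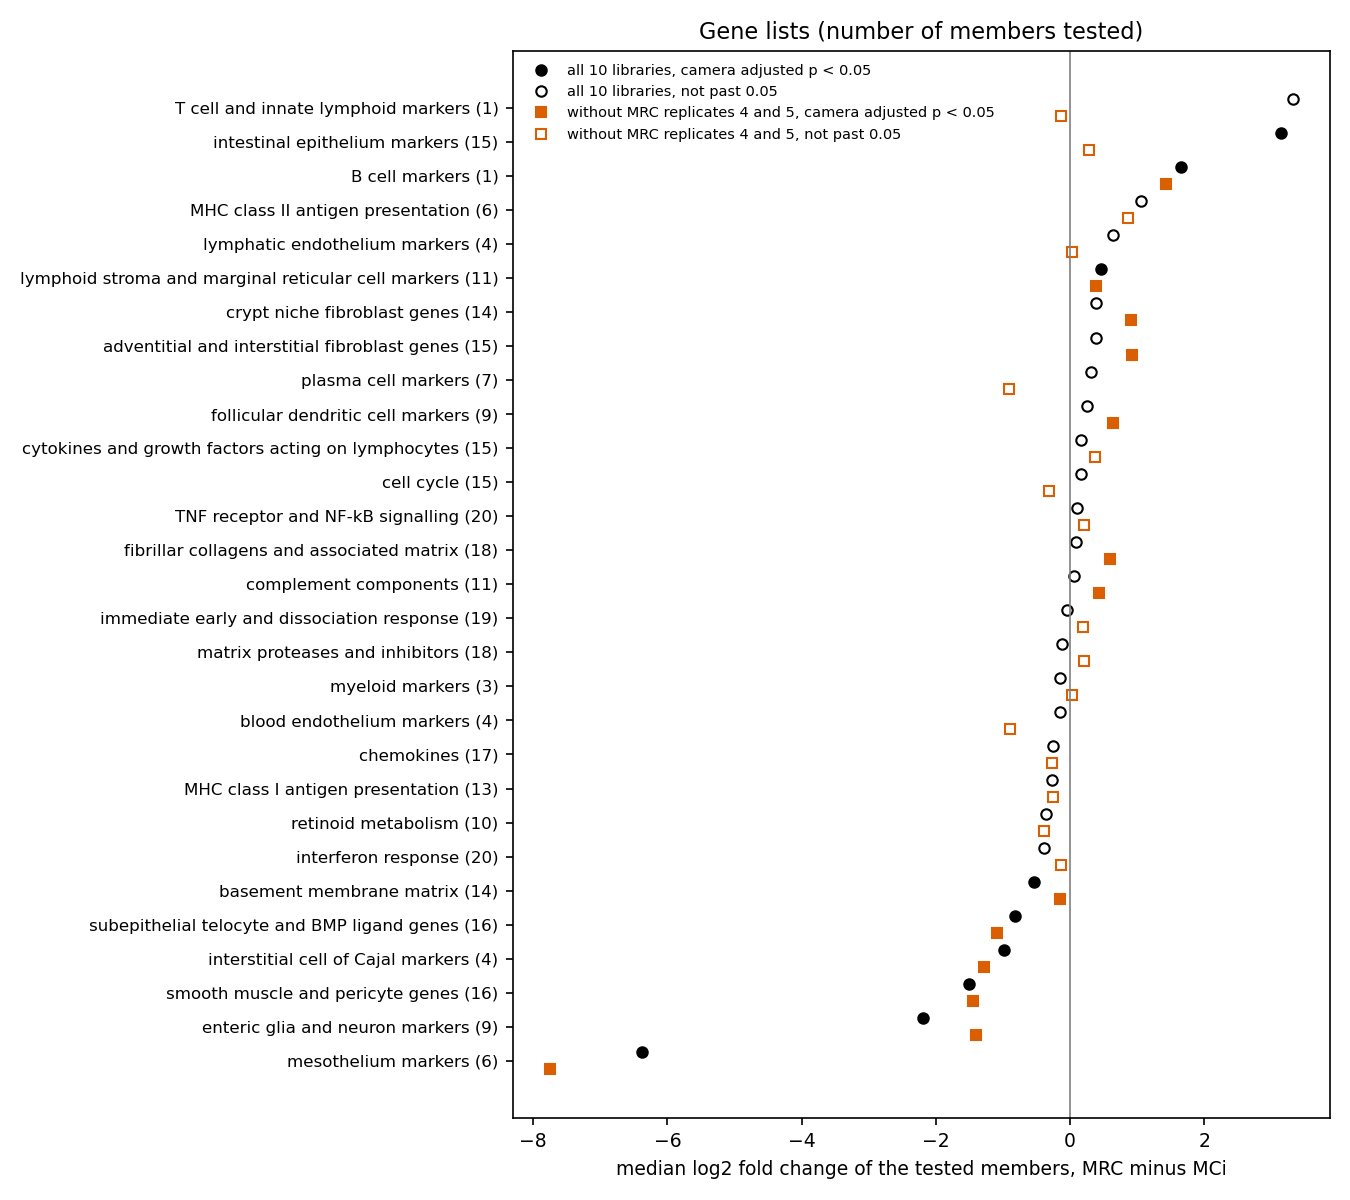
Median log2 fold change (MRC minus MCi, horizontal axis) of 29 gene lists, over all 10 libraries (black circles) and without MRC4 and MRC5 (orange squares). Filled symbols have a camera adjusted p under 0.05; the mesothelium list lies lowest at −6.37 and the epithelial list moves from 3.14 to 0.29 when the 2 libraries are left out.

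Several fibroblast and stromal lists did not pass over all 10 libraries but passed when MRC4 and MRC5, the libraries high in epithelial transcripts, were left out, an alternative chosen after the data were seen. Over all 10 libraries, 0 of 15 adventitial fibroblast genes, 14 crypt niche genes, 18 fibrillar collagen genes and 11 complement genes passed in edgeR, 1, 2, 1 and 1 had an unadjusted p under 0.05, and DESeq2 called 1 in each. Their camera adjusted p was 0.295, 0.635, 0.661 and 0.635. The adventitial gene that DESeq2 called, Dpp4, was at 9.08, 9.58, 133, 637 and 875 CPM in MRC 1 to 5, highest in MRC4 and MRC5. Without the 2 libraries, these lists and the follicular dendritic cell list had camera adjusted p of 1.24e-10, 4.11e-06, 2.25e-07, 0.000897 and 0.00135, but adjusted p = 0.106, 0.106, 0.150, 0.157 and 0.106 with an estimated correlation. Over 29 alternatives, adjusted p for these 5 lists reached 0.833, 0.953, 0.980, 0.940 and 0.682, and the values without the 2 libraries were the lowest. The adventitial list also passed without MRC4 alone (camera adjusted p = 0.0173) or MRC5 alone (0.00224). Leaving out MRC4 and MRC5 kept MCi4 and MCi5 in the MCi group. Their adventitial scores were 7.70 and 7.54, against 8.32 to 8.73 in MCi 1 to 3. Crypt niche scores were 6.31 and 6.24 against 6.75 to 7.02, and collagen scores 10.1 and 10.1 against 10.3 to 10.8. Their complement and follicular dendritic cell scores lay within the range of MCi 1 to 3. What this imbalance added to the calls was not tested. Col14a1, a fibril-associated collagen gene, was at 2208, 2229, 2138, 471 and 519 CPM in MRC 1 to 5 and averaged 903 ± 113 CPM (SD, n = 5) in MCi. Adjusted over the list alone, 1 collagen list gene (Col12a1) and 1 complement gene (Cd59a) were higher in MCi, and 0 of the adventitial or crypt niche genes passed. For the fibrillar collagens the median (0.09) and mean (0.04) were above 0 while the test pointed down, and for complement the median was 0.06, the mean −0.07 and the test down.

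Immune signalling, matrix turnover and stress lists did not pass over all 10 libraries. Camera adjusted p was 0.295 for 20 TNF receptor and NF-kB genes, 0.882 for 15 cytokines and growth factors, 0.909 for 17 chemokines, 0.295 for 18 matrix proteases and inhibitors, 0.0712 for 20 interferon response genes, 0.200 for 13 MHC class I genes, 0.107 for 6 MHC class II genes, 0.995 for 19 immediate early genes and 0.479 for 15 cell cycle genes. In these lists 0 members passed in edgeR over all genes; 3, 2, 3, 1, 3, 1, 0, 0 and 0 had an unadjusted p under 0.05, and DESeq2 called 2 NF-kB genes and 3 chemokine genes. Adjusted over the list alone, 2 chemokine genes, Cxcl13 and Ccl19, passed and no other member of these lists did. Ccl25, the other chemokine gene that DESeq2 called, was at 0.717, 14.8, 180, 993 and 714 CPM in MRC 1 to 5, highest in MRC4 and MRC5. The interferon list, with a median of −0.38, passed without MCi1 (camera adjusted p = 0.000347), MRC2 (0.0110) or MRC3 (0.0102), within 0.000347 to 0.793 over 29 alternatives. The MHC class I list (median −0.27) passed without MCi1 (0.0128, within 0.00758 to 0.793), and the MHC class II list (median 1.05) without MCi2 (0.0106) or MRC1 (0.00654, the lowest of its alternatives, which reached 0.735). In all, the interferon, MHC class I and MHC class II lists passed in 9, 4 and 6 of 29 alternatives. Of these passes, 3, 1 and 2 were fits that left out 1 library. The chemokine median was −0.26 while its mean (0.22) and test pointed up, and the immediate early median (−0.04) and mean (−0.05) lay below 0 while the test pointed up. The interferon-inducible GTPase gene Iigp1 averaged 700 ± 284 CPM (SD, n = 5) in MCi and 336 ± 226 CPM in MRC (edgeR adjusted p = 0.320). The MHC class II invariant chain gene Cd74 averaged 65.0 ± 51.2 and 179 ± 106 CPM (edgeR adjusted p = 0.335). Among other cell types, 7 plasma cell, 1 T and innate lymphoid, 3 myeloid, 4 blood endothelial and 4 lymphatic endothelial markers had camera adjusted p of 0.909, 0.635, 0.333, 0.295 and 0.298. Of these markers 0 passed in edgeR over all genes, 0, 0, 0, 1 and 2 had an unadjusted p under 0.05, and DESeq2 called 1 blood and 1 lymphatic endothelial marker; adjusted over the list alone, 1 of these, the endothelial adhesion gene Esam, was higher in MCi.

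Over all 12127 genes tested, edgeR called 53 at an adjusted p under 0.05, 9 higher in MRC (17.0%) and 44 higher in MCi, with 2023 at an unadjusted p under 0.05. In 460 genes (3.79%) the groups did not overlap, where chance gives 0.794%. DESeq2 called 851 genes, 550 of them (64.6%) higher in MRC, and included all 53. On log2(RPKM + 1) limma called 244 genes, 6.15% of them higher in MRC, with the median of all genes at −0.21 against 0.01 in edgeR. Without MRC4 and MRC5, edgeR called 128 genes, 47 higher in MRC and 81 higher in MCi, of which 47 were among the 53. The 6 lost were Msln, Slpi, Gpm6a, Sv2b, Plet1 and Rerg, the last named after its values were seen. Their log2 fold changes were −9.99, −9.43, −7.82, −5.08, −5.03 and −2.17 without the 2 libraries, against −8.60, −8.06, −7.58, −5.82, −5.82 and −2.40 over all 10. Leaving out 1 library gave 19, 23, 33, 23 and 16 genes without MCi 1 to 5 and 34, 33, 21, 49 and 49 without MRC 1 to 5, and 15 of the 53 passed in all 10 fits. The 4 libraries numbered 4 or 5 were deeper than the 6 numbered 1 to 3, and the labels do not say whether they were prepared apart. In alternatives chosen after the data were seen, edgeR called 95 genes in replicates 1 to 3 alone and 3460 in replicates 4 and 5 alone. With these library sets as a covariate it called 206, all 53 among them. The 3460 came from 2 libraries per group. MCi4 and MCi5 were the closest pair (r = 0.973), and MRC4 and MRC5 were highest in epithelial transcripts. Spread within these pairs may be technical, so that count is not set against the others.

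Pairs of MCi libraries correlated with a mean r of 0.902 (range 0.872 to 0.973, log2 CPM across genes, which are not independent replicates), pairs of MRC libraries with 0.766 (0.579 to 0.916) and pairs between groups with 0.790 (0.544 to 0.917). Without MRC4 and MRC5, pairs between groups had a mean r of 0.876, and pairs among MRC 1 to 3 one of 0.877. The first principal component held 60.3% of the variance and placed MRC4 and MRC5 farthest to one side, at 134 and 137. The other 8 libraries were spread along it, from −80.3 (MCi3) to 25.5 (MRC3). MCi1, MCi3 and MRC1, lowest in epithelial score (0.615, 0.0201 and −0.315), lay lowest on it (−76.3, −80.3 and −72.4). MCi4 and MCi5 were the closest pair (r = 0.973), and their counts differed beyond sampling noise (chi-square per degree of freedom 7.77, against 20.8 or more for other pairs). Separate amplifications of 1 RNA would also differ beyond that noise, so this does not show that they came from separate animals. Each was counted as 1 library, as labelled, and with either left out 23 (without MCi4) or 16 (without MCi5) genes passed.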

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

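Of the tests below, those of stromal expression, depth, dilution, mesothelial cells for the muscle and BMP genes, epithelial RNA for the follicular dendritic cell genes and B cells were chosen after the result was seen.

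Among 125 named genes, 29 list scores and 6 library measures, 21 of 320 groups of 5 libraries had 1 library whose gap to its neighbour exceeded 0.71 of the range of the group, where chance gives about 1 in 20, or 16. In MRC4 the intron share of gene reads was 10.8%, against 4.75% to 5.26% in the other MRC libraries. MRC4 also stood apart with Clu at 6875 CPM, Ugt1a6a at 96.3 CPM, Lyz2 at 0.472 CPM and Lrrn4 at 4.25 CPM. MRC5 stood apart in the TNF receptor and NF-kB score (5.42), Slpi (3.97 CPM), Hspa1a (74.3 CPM) and Upk3b (1.19 CPM), and MRC3 in Plet1 (0.874 CPM). MCi1 was low in the MHC class I score (7.60) with H2-Q7 at 173 CPM, Tap1 at 77.9 CPM, Iigp1 at 229 CPM and C2 at 86.7 CPM, and set apart in the lymphatic endothelial score (6.96). MCi3 was high in the glial and neuronal score (4.96), with Sox10 at 85.4 CPM and Fgf9 at 24.9 CPM, and low in Xbp1 (319 CPM) and Sdc1 (57.9 CPM). Outside the exon counts used for the comparison, the mitochondrial ribosomal RNA gene mt-Rnr2 held 2.08% of gene reads in MRC4 and 0.642% in MRC5, against 0.0905% to 0.294% in the other 8 libraries.

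Epithelial transcripts were high in MRC4 and MRC5. Expression of epithelial genes by MAdCAM1-positive stroma in general would place every MRC library above every MCi library, but 16 of 25 pairs had the MRC library higher; expression by the stroma of these 2 libraries alone was not tested. Depth is argued against by MCi5, which is deeper than both and lies 3.63 log2 units below the lower of them in epithelial score. Epithelial cells or their RNA carried through the sort, although EpCAM1-positive cells were gated out, remain a candidate source. Of 15 fixed markers, 14 were above 10 CPM in both libraries, with Fabp2 at 4843 and 8582 CPM. The same markers showed the pattern, so this count cannot tell carried-over RNA from expression by the stroma of these libraries. One of the 15 markers, Krt19, is also on the mesothelium list.

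Genes were higher in MCi. For dilution of MRC libraries by epithelial RNA, the median log2 fold change of the 44 genes without MRC4 and MRC5 was −2.36. These genes were called partly on MRC 1 to 3, so a value below 0 was likely beforehand. The muscle and BMP lists, fixed in advance, had medians of −1.45 and −1.08 without the 2 libraries. That argues against dilution in MRC4 and MRC5 as the cause for these lists. MRC3 still held Epcam at 107 CPM, and dilution there was not tested. Mesothelial cells in the MAdCAM1-negative gate may account for the mesothelium genes, where 4 of the 5 tested members other than Msln lay below 0 with a median of −5.16, and Msln itself reached 232 CPM. They are argued against for the muscle and BMP genes: the mean score of both lists spanned 0.301 log2 units over the MCi libraries while the mesothelium score spanned 5.90, and MCi was higher in 25 of 25 library pairs; the order of the MCi libraries alone, alike in 6 of 10 pairs, had not decided it. Smooth muscle cells or pericytes in that gate, although the sort kept podoplanin-positive cells, and a difference between the sorted stromal populations cannot be told apart, since 7 muscle and pericyte markers had a median of −0.96 without the 2 libraries with only 5 of 7 below 0, and Des and Rgs5, abundant in such cells, were at 151 and 562 CPM in MCi and 186 and 536 CPM in MRC.

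The follicular dendritic cell genes Clu and Mfge8 were higher in MRC. For epithelial RNA as the whole cause, their median log2 fold change without MRC4 and MRC5 was 1.71. Both genes were called partly on MRC 1 to 3, so a value above 0 was likely beforehand and decides nothing. In MRC1, with Epcam at 0.239 CPM, Clu was at 2867 CPM and Mfge8 at 4576 CPM. The highest MCi values were 839 and 1411 CPM. For MRC1 alone, epithelial RNA is thus argued against. For MRC 1 to 3, B cells are argued against by Cd79a, an abundant B cell gene, which reached at most 0.239 CPM there. This check did not cover MRC4 and MRC5, where Ptprc was at 3.31 and 10.9 CPM. Follicular dendritic cells within the MAdCAM1-positive gate and expression by the other sorted stroma were not tested against each other.

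The count of 53 genes was set against other splits of the 10 libraries into 5 and 5. Of 100 splits drawn from 126, 1 gave as many genes, the real one, and the highest of the others gave 1. The count is thus larger than other divisions of these libraries gave. The splits treat the libraries as independent, which the labels do not state, so chance differences between animals or preparations are not excluded.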

How the results depend on the processing

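Leaving out MRC4 and MRC5, unique exon reads, gene reads, the epithelial score as a covariate, the library sets and their covariate were chosen after the data were seen. Where a value moved, the cause was not tested unless stated. The main count was 53 genes, 9 higher in MRC and 44 higher in MCi, and these 53 had the same sign in each setting that tested them. DESeq2 called 851 (550 and 301). Limma on RPKM called 244 (15 and 229) with a pseudocount of 1, 159 (11 and 148) with 0.1 and 149 (8 and 141) without a filter. Without MRC4 and MRC5 the count was 128 (47 and 81), and with the epithelial covariate 136 (49 and 87). It was 95 (28 and 67) in replicates 1 to 3 only, and 206 (63 and 143) with the library set as a covariate. In replicates 4 and 5 only, with 2 libraries per group, it was 3460 (2053 and 1407). Gene reads gave 14 genes higher in MRC. At an adjusted p under 0.01, 12 genes passed (2 and 10), by the stricter threshold. Leaving out 1 library gave 16 to 49 genes, 2 to 10 higher in MRC and 14 to 41 higher in MCi, with fewer samples in each fit.

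Of the lists, 9 passed, among them the B cell list of 1 gene, against 14 in replicates 1 to 3 only, 2 with an estimated correlation and 5 with fry. The mean r between groups was 0.790, and 0.926 without a filter or 0.917 on RPKM without a filter, where more genes near 0 were included. Lists were counted as reversed if the direction changed and the main or the alternative setting passed. These were the fibrillar collagens (median 0.59 without MRC4 and MRC5, 0.34 in replicates 1 to 3), complement (0.43 and 0.48), the immediate early genes (−0.20 in replicates 1 to 3) and the epithelial list. The epithelial test pointed down without MRC4 and MRC5 at a median of 0.29. Other lists changed direction but passed in neither setting, such as cell cycle (median 0.16, and −0.31 without MRC4 and MRC5). In replicates 4 and 5 only, the fibrillar collagen and complement lists passed toward MCi (medians −0.87 and −0.87), and Col14a1 (−1.05) and Col3a1 (−0.86) reversed. Over 123 tested named genes, 2891 of 3272 alternative values stayed on their side of the threshold without being counted as reversed. Of the others, 196 passed newly, 182 no longer passed and 3 reversed. Over 29 lists the numbers were 782 of 839, 32, 19 and 6. The values that stayed include 2970, over genes and lists, that passed in neither setting. Of these 2970, 116 changed direction.

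With the replicate number as a block, 49 genes passed (15 and 34), and 64 (21 and 43) with the exon length correction, 25 of the 53 in each. Correlations of the deviations of same-numbered libraries were 0.558, −0.254, 0.0624, 0.346 and 0.485, 3 of 5 over 0.1, so the rule set in advance, which asked for all 5, took the libraries to share only a number. Of 5 MCi libraries, 2 correlated best with the MRC library of their own number, and MCi4 and MCi5 both with MRC5. Whether the libraries numbered 4 and 5 share a preparation is not given in the labels and stays open. Depth limits low genes: Tnfsf11, at 0 to 2.90 CPM, was near the floor of 0.343 to 0.761 CPM.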

Other observations

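The genes in this part were named after their values were seen, except Bmp7 and Bst1, and the fits without MRC4 and MRC5 were chosen after the result was seen.

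The 44 genes higher in MCi over all 10 libraries included several receptor genes, for which no list was fixed or tested. The endothelin A receptor gene Ednra averaged 267 ± 95.1 CPM (SD, n = 5) in MCi and 69.9 ± 28.7 CPM in MRC, and Ece1, which encodes an endothelin-converting enzyme, 385 ± 84.3 and 190 ± 6.12 CPM (edgeR adjusted p = 0.0363 and 0.0333). The apelin receptor gene Aplnr averaged 102 ± 36.5 and 13.5 ± 6.08 CPM, the bradykinin receptor gene Bdkrb2 42.4 ± 18.7 and 8.17 ± 2.56 CPM, and Ramp1, a subunit of the receptor for the neuropeptide CGRP, 62.5 ± 16.8 CPM in MCi with a log2 fold change of −2.84 (edgeR adjusted p = 0.00483, 0.0218 and 0.00382). The thrombin receptor genes F2r and F2rl3 averaged 593 ± 189 and 10.4 ± 2.93 CPM in MCi against 188 ± 42.1 and 1.86 ± 0.316 CPM in MRC (edgeR adjusted p = 0.0286 and 0.00916). Cav1, which encodes the caveolar coat protein caveolin, averaged 191 ± 40.0 and 25.5 ± 6.61 CPM, with an edgeR adjusted p of 0.00106, as low as that of Bmp7. The limb and lung mesenchyme factor gene Tbx4 averaged 14.0 ± 2.69 and 1.38 ± 0.728 CPM (edgeR adjusted p = 0.00483). Of these, Aplnr, Cav1, F2rl3, Ramp1 and Tbx4 passed in all 10 edgeR fits that left out 1 library, F2r and Bdkrb2 in 4 of 10, Ednra in 1 and Ece1 in 0.

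Without MRC4 and MRC5, 81 genes passed that had not passed over all 10 libraries, 38 higher in MRC and 43 higher in MCi. Higher in MRC were the cystine transporter gene Slc7a11 (log2 fold change 3.52), the lipoprotein receptor gene Vldlr (2.10), the guidance ligand gene Slit2 (1.77), the growth factor gene Tgfb3 (0.98) and Bst1 (2.02), with edgeR adjusted p of 0.0227, 0.00673, 0.00709, 0.0249 and 0.0361. For Bst1, 27 alternatives gave 1.57e-06 to 0.170. Higher in MCi were Wnt5a (−1.77), the activin subunit gene Inhbb (−3.21), the hedgehog-binding protein gene Hhip (−1.44) and the retinaldehyde dehydrogenase gene Aldh1a1 (−1.02), with edgeR adjusted p of 0.0181, 0.00673, 0.0301 and 0.0206. Over all 10 libraries their adjusted p ranged from 0.0632 for Inhbb to 0.829 for Aldh1a1. For Slit2, Vldlr, Tgfb3 and Aldh1a1 the mean of MRC4 and MRC5 lay on the opposite side of the MCi mean. Slit2 averaged 148 CPM in MRC 1 to 3 but 91.5 CPM over all MRC libraries, against 43.7 CPM in MCi. Aldh1a1 averaged 269, 468 and 546 CPM in the same order. For Slc7a11, Bst1, Wnt5a, Inhbb and Hhip the mean of MRC4 and MRC5 lay on the called side. The common coefficient of biological variation was 0.495 over all 10 libraries and 0.369 without the 2.

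Tgtp1 was higher in MCi (59.3 ± 10.5 against 6.79 ± 4.61 CPM, SD, n = 5, edgeR adjusted p = 0.00916), but a near-identical neighbouring copy, Tgtp2, makes its reads uncertain. The interferon response list it would belong to did not pass (camera adjusted p = 0.0712).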
